A study of Mus musculus with 2 samples.

How the data were processed

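Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in the facial prominence of mouse embryos at day 15.5. There was 1 group with 2 replicates. Per the labels, replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62 embryos, of both sexes. With no other tissue, stage or condition, no comparison between groups was possible.

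The deposited files were peak lists on the mouse build mm10. Each line held an interval, a summit and the peak caller's own values. The authors deposited an enrichment ratio over local background for each summit, together with −log10 p and −log10 q values. These are the authors' values for a peak within its own list. They were used to rank, filter and describe peaks, except for the correlation and the ratio between the replicates, which set the ratios of separately made lists side by side. Per the deposited read-me text, the lists derived from the alignments of each replicate or of both. The aligner, the peak caller and their versions are not given in the sources used here, and neither is how reads were shifted or filtered. The files held no read counts, so the depth of each library is unknown and no counting interval could be given. A peak list is bounded by depth: a gene with no region was below the list's threshold, which does not show that its chromatin was closed.

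The main lists were those the authors had filtered by the irreproducible discovery rate (IDR), a measure of agreement between repeated peak calls. For each replicate these rested on partitions of its own reads, and for the series on both replicates. Several summits often shared an interval, so each non-overlapping interval was counted as 1 region with its strongest summit. Chromosomes 1 to 19, X and Y were used. Chromosome lengths of the GRCm38.p6 reference matched the build of the files, in that no peak ended past a chromosome.

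Genes came from GENCODE M21, with 21853 protein-coding genes on these chromosomes. A promoter region had its summit within 1 kb of a protein-coding transcription start site (TSS). All other regions were distal and were given to the nearest TSS within 100 kb. Exons, introns and intergenic sequence were also defined by protein-coding genes alone, so promoters of noncoding genes could count as distal. The share of each class in the genome was counted outside assembly gaps. The 28 gene lists, 27 consensus motifs, tests, alternative settings and the rule for named genes were fixed before the data were examined. Of the lists' symbols, 2 matched no gene.

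For distal regions, the mean number per gene was compared with 10000 random lists of the same size matched on deciles of territory length, the stretch nearest to a gene's TSSs. For promoters, the share of genes with a region was compared with all other genes by Fisher's exact test. For motifs, the share of distal summits with a match within 50 bp was compared with the mean of 2 flanking windows centred 500 bp away, by flipping the signs of chromosome differences 100000 times. All tests were two-sided and were run in each replicate separately, with Benjamini-Hochberg adjustment over lists or motifs. A list or motif was called only with an adjusted p under 0.05 in the same direction in both replicates. Genes and regions are not replicates, so these tests concern the placement of regions in these libraries. Genes in clusters, such as the Hox genes, are not independent of each other. The smallest p the random lists can give is 0.0002, and 1e-05 for the sign flips. A list that was called in neither the main setting nor an alternative was counted as unchanged.

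The scripts were tested on simulated data. For distal lists over 21853 genes, a planted 10-fold difference was called in 81% of 100 lists, a 5-fold difference in 46%, a 3-fold difference in 15%, a 2-fold difference in 1% and a 1.5-fold difference in 0%, against 0% of 1560 lists with no difference. In that setting the test of distal lists thus had little power below about 5-fold, and a list that was not called may still differ. The simulated spread of regions over genes was chosen and not fitted to the data, and both replicates shared it. Placement followed territory length, on which the test matches. The rates for the real lists may therefore differ from these. For promoter lists, planted high and low shares were called in 96.7% and 85% of 60 lists each, against 0.682% of 440 unplanted lists. The planted shares lay far from the background, and the promoter window was narrower than in the data. The same simulated regions stood for both replicates, so agreement between replicates was not part of that test. Planted motifs were called in 100% of 10 tests and unplanted ones in 0% of 125. The simulated sequence had the same base composition at summits and flanks, and each call used a single library. The motif rates therefore do not cover the difference in GC content between real summits and flanks.

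The named genes were the 15 with most distal regions of the series list, the 3 with most in each gene list and, in lists called for promoters, up to 3 genes without a promoter region. The named regions were the 10 distal regions with the highest mean enrichment and the 5 with the largest ratio in favour of each replicate. Alternative settings were other deposited lists, a stricter IDR of 0.01, the stronger 50% of regions, other promoter windows, reaches, motif windows and overlaps, the longest transcript only, a reversed motif as background and leaving out each replicate. Leaving out regions that resemble mitochondrial DNA and counting every summit were added after seeing the data. Windows of 201 bp around summits were matched to the mitochondrial sequence (at least 80% identity over 100 bp) and, for named regions, to the nuclear genome (at least 95% over 150 bp) with BLAST+ 2.17.0. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.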

Results

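The facial prominences, which form the jaws, palate and nose, were profiled by ATAC-seq at embryonic day 15.5 in 2 pools of whole tissue. Accessible chromatin was described by the deposited peak lists, whose enrichment values are the authors' own, and the depth of each library is unknown. The series list, which rests on both replicates, held 38265 summits in 16646 regions with a median width of 822 bp, covering 0.511% of the genome. Replicate 1 alone gave 12638 regions and replicate 2 alone 13058 regions, both with a median width of 767 bp. The median enrichment of a region was 7.83 in replicate 1 and 8.71 in replicate 2.

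To ask how far the pools gave the same regions, their lists were overlapped by at least 1 bp. Of the regions of replicate 1, 85.0% overlapped a region of replicate 2, and 82.1% overlapped in the other direction, a mean of 83.6% ± 2.03 (SD, n = 2 directions). Across the shared regions, which are not independent replicates, log2 enrichment correlated with Spearman's rho of 0.87 and Pearson's r of 0.86. Distal regions were shared less often than the whole list, with 1966 of 3083 in replicate 1 and 1966 of 3353 in replicate 2. This difference was not tested.

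Promoters dominated the accessible regions. Summits within 1 kb of a protein-coding TSS made up 74.96% ± 0.907 of regions (SD, n = 2), 30.8-fold over their 2.44% of the genome. Introns of protein-coding genes held 9.04% ± 0.336 of regions and sequence outside these genes 14.6% ± 0.582 (SD, n = 2 each), against 34.4% and 60.1% of the genome. Exons held 1.41% ± 0.0106 (SD, n = 2). The promoter share depended on how many regions were kept, since it was 37.1% in the longer pseudoreplicated lists and 90.2% in the stronger 50% of regions.

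Housekeeping promoters were accessible almost throughout, and promoters of the Hox, blood, germline, gut and pancreas, liver and eye lists were rarely so. A region lay at the promoter of 25 of 26 housekeeping genes in both replicates (96.2%), among them Actb, Gapdh and Tbp, against 45.9% and 46.6% of other genes. The exception was Psmb4, which encodes a proteasome subunit. No promoter region was found at any of the 27 Hox genes of groups 5 to 13, which pattern the trunk and limbs, or of the 12 of groups 1 to 4, in either replicate, although the series list had a region with an enrichment of 3.93 at Hoxc13. The erythroid list (19 genes, including Gata1, Klf1 and Hba-a1) and the leukocyte list (24 genes, including Ptprc, Spi1 and Csf1r) also had none. Germline genes (4.17% in both replicates), gut and pancreas genes (5% in both), liver genes (8.33% in both) and eye genes (5% and 10%) followed. In the liver list Alb and Afp had no promoter region, while Foxa3 had an enrichment of 9.88 in replicate 1 and 11.3 in replicate 2. Ddx4 of the germline list, Pdx1 of the pancreas and Pax6 of the eye had none.

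Markers of skeletal muscle, endothelium and epithelium were also below other genes. Skeletal muscle genes had a promoter region in 11.5% of cases in both replicates, and the myogenic regulators Myod1, Myf5 and Myf6 had none. Endothelial genes had one in 13.6% and 18.2%, with Pecam1 and Cdh5 among those without and Ets1 reaching 11.8 and 13.1 in enrichment. Epithelial genes had one in 20.8% in both, with Trp63, Krt5 and Krt14 without, although Perp reached 5.14 and 6. In total 11 lists were lower and 1 was higher in both replicates by Fisher's exact test with Benjamini-Hochberg adjustment over 28 lists, and the largest adjusted p among the lower lists was 0.0319. The calls for muscle, endothelium, epithelium and Hox groups 1 to 4 ended in the pseudoreplicated lists, and that for epithelium also with a 2500 bp window and with the longest transcript only. When lists were compared with genes of matched promoter CpG content, the calls for muscle, liver and leukocyte genes ended, with a matched share of 4.5% for leukocyte genes in replicate 1.

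**Figure D1:**
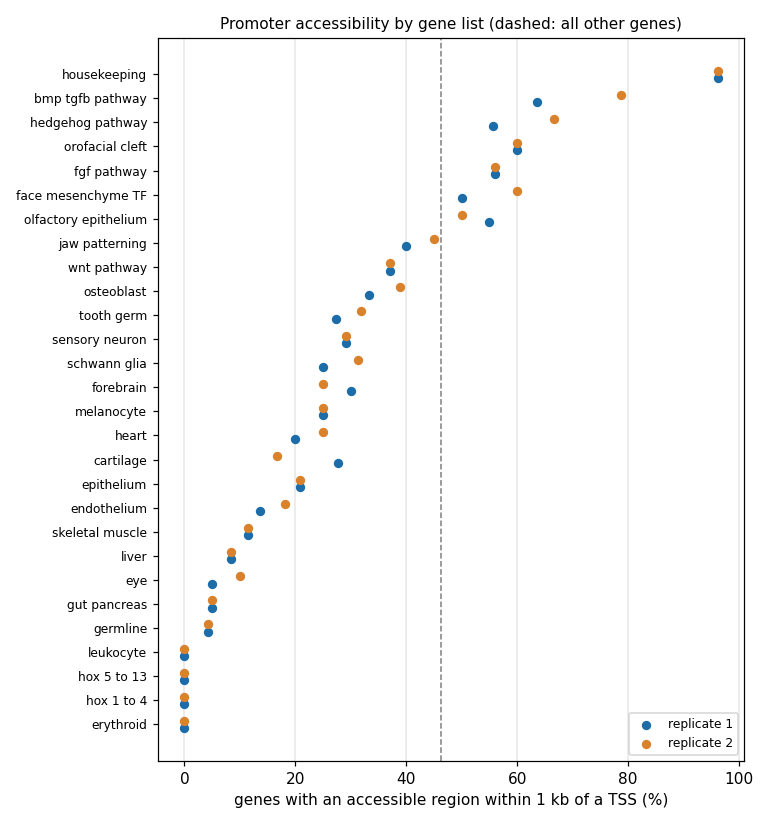
Share of each list's genes with an accessible region within 1 kb of a TSS (horizontal axis, percent) in replicate 1 and replicate 2, with the mean of all other genes as a dashed line. Housekeeping genes lie at 96.2% in both replicates, and the erythroid, leukocyte and both Hox lists lie at 0.

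The other lists were not called by the same test, but several were higher or lower in other settings. Transcription factors of the facial mesenchyme and genes of orofacial clefting and of the BMP and TGF-beta pathway were called higher in the pseudoreplicated lists, and those of the BMP and TGF-beta pathway also with a 2500 bp window, the longest transcript only and every summit. Jaw patterning, cartilage and forebrain genes were called lower in the stronger 50% of regions, forebrain and heart genes with a 500 bp window, and tooth germ and Schwann cell genes with the longest transcript only. Against genes of matched CpG content, jaw patterning, sensory neuron, forebrain and WNT pathway genes were called lower in both replicates, jaw patterning with 40% and 45% against 69.4% and 70.3% (adjusted p = 0.0196 and 0.0366 by permutation). With this matching, facial mesenchyme factors had 50% and 60% against 70.5% and 71.7%, and clefting genes 60% in both against 67.9% and 68.9%. BMP and TGF-beta genes had 63.6% and 78.8% against 70.7% and 71.6%. None of these lists was called higher or lower this way. The matching was not run on the pseudoreplicated lists, so CpG content may account for the higher calls there. Transcription factors of the facial mesenchyme had a promoter region in 50% and 60% of cases (adjusted p = 0.716 and 0.256, Fisher's exact test). Snai1, a regulator of neural crest migration, reached an enrichment of 11.4 in replicate 1 and 12.8 in replicate 2, and Six1 7.2 and 7.42. Genes of orofacial clefting stood at 60% in both replicates, hedgehog pathway genes at 55.6% and 66.7%, and FGF pathway genes at 56% in both. Olfactory genes stood at 55% and 50%, jaw patterning genes at 40% and 45%, WNT pathway genes at 37.1% in both, osteoblast genes at 33.3% and 38.9% and tooth germ genes at 27.3% and 31.8%. Forebrain genes had 30% and 25%, sensory neuron genes 29.2% in both, Schwann cell genes 25% and 31.2%, melanocyte genes 25% in both and heart genes 20% and 25%. Genes of the BMP and TGF-beta pathway (63.6% and 78.8%) and of cartilage (27.8% and 16.7%) passed the threshold in replicate 2 alone, with adjusted p = 0.000964 and 0.0312 by Fisher's exact test.

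Genes of 4 lists had more distal regions than matched genes. Osteoblast genes carried 13 distal regions in each replicate, 4.34-fold and 4.08-fold over matched random lists. Col1a1 (chromosome 11, 94936224 to 94953042), which encodes type I collagen, had 4 of them in each replicate, as did Col1a2, and Sp7, a transcription factor required for bone formation, had 3 in replicate 1 and 2 in replicate 2. Genes of the BMP and TGF-beta pathway had 25 and 27 regions, 3.87-fold and 3.91-fold over matched lists. The inhibitory Smad7 (chromosome 18, 75367529 to 75395935) had 5 in replicate 1 and 6 in replicate 2, Smad6 had 3 in each, and the receptor gene Tgfbr2 had 0 and 2. Hedgehog pathway genes had 14 and 17 regions (4.14-fold and 4.7-fold), among them 2 and 3 at Gli2, 2 and 3 at Hhat and 2 in each replicate at Gas1. FGF pathway genes had 15 and 16 regions (3.26-fold and 3.24-fold), among them 2 and 3 at the receptor gene Fgfr1, 2 in each replicate at Fgfr2, and 0 and 1 at Fgf18. Over both replicates together, the series list had 7 regions at Col1a1, 4 at Col1a2, 3 at Sp7, 7 at Smad7, 6 at Smad6, 5 at Tgfbr2, 4 each at Gli2, Fgfr1 and Fgfr2, and 3 each at Gas1, Hhat and Fgf18.

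These 4 lists of 28 passed the permutation test over random lists in both replicates, with adjusted p between 0.0056 and 0.0238, and none was lower. A lower call was hardly possible in this setting, since the central 95% of random lists reached 0 for most lists. Even lists with 0 regions, such as liver genes in replicate 1, lay inside that range. The 4 calls rest on few regions. The osteoblast and FGF calls ended when every summit was counted, and the cause of that was not tested. In the stronger 50% of regions none of the 4 was called, but between 0.557 and 1.36 regions per list were expected there and 0 to 2 were found, too few to weigh the calls. The osteoblast call also ended in the pseudoreplicated lists, and the FGF call with the longest transcript only, with a reach of 500 kb and when matched on promoter regions as well (adjusted p = 0.0803 in replicate 1 by permutation). All 4 calls ended when the gene with most regions was left out of the list alone, and all 4 held when each random list lost its top gene too. The former version leans towards ending calls and the latter towards keeping them. In the main test WNT pathway genes passed in replicate 2 alone (2.98-fold, adjusted p = 0.0149 by permutation), against 2.45-fold and adjusted p = 0.0864 in replicate 1. Wnt7b carried 2 regions in replicate 1 and 4 in replicate 2. With the top gene left out of list and random lists alike, WNT genes passed in both replicates (3.16-fold and 3.55-fold, adjusted p = 0.0289 and 0.0098 by permutation). Jaw patterning (2.72-fold and 2.06-fold), orofacial clefting (2.69-fold and 2.05-fold) and olfactory genes (3.11-fold and 2.12-fold) lay above matched lists without passing. In the longer pseudoreplicated lists jaw patterning (adjusted p = 0.00448 and 0.014), orofacial clefting (adjusted p = 0.0312 and 0.0028) and WNT pathway genes (adjusted p = 0.0028 in both) passed the same permutation test in both replicates. Mesenchymal transcription factors lay at 0.67-fold and 1.56-fold. The test called 15% of simulated 3-fold lists, so differences of that size can go unseen here.

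**Figure D2:**
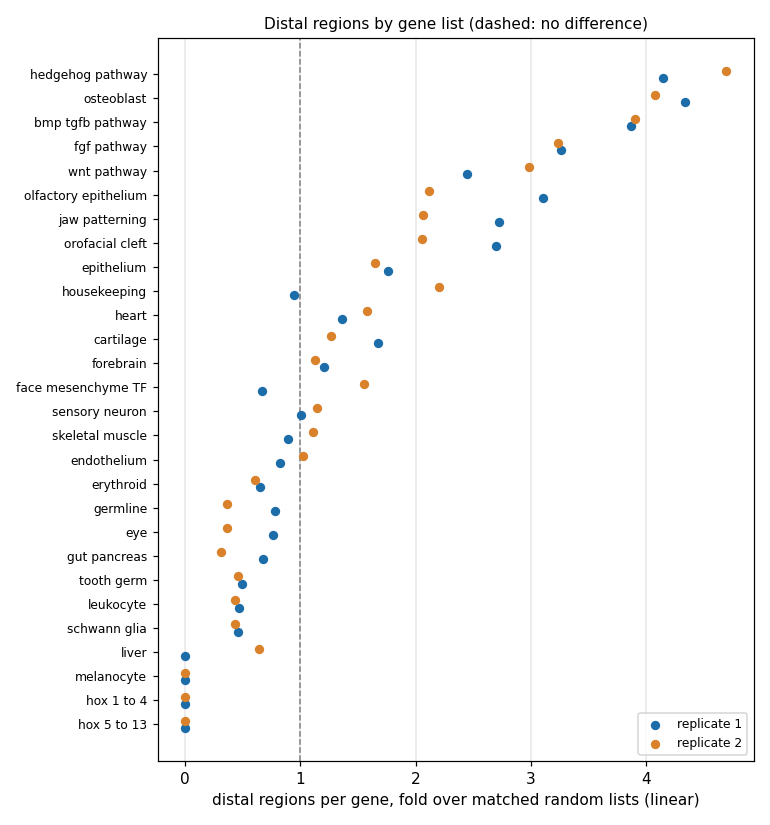
Distal regions per gene as fold over matched random lists (horizontal axis, linear) for each gene list in replicate 1 and replicate 2, with the dashed line at no difference. The hedgehog, osteoblast, BMP and TGF-beta, and FGF lists lie above 3-fold in both replicates.

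Over all genes, Sfi1 had the most distal regions of the series list, with 13, of which 3 have a near-identical copy elsewhere in the genome, so its count is uncertain. The same holds for 3 of the 7 at Scaf8. Ncor2, a corepressor gene, and Rgs3 followed with 9 each, and Mef2c, Trio and 2010111I01Rik with 8 each. Col5a1, Gse1, Igf2r, Ncam1, Sh3pxd2a and 1700001O22Rik had 7 each, as did Col1a1, Scaf8 and Smad7. These counts and their order depended on the list. In replicate 1 and replicate 2 taken alone, Sfi1 had 9 and 5, Mef2c 6 and 2, Smad7 5 and 6, Trio 3 and 6, Rgs3 3 and 3, and Ncor2 2 and 4. The other 9 had between 1 and 5. At an IDR of 0.01, 9 of the 15 genes moved by over 1.5 times, such as Ncam1 to 2 and Col5a1 to 3. In the replicated list 14 of the 15 moved, and Gse1 with 29 and 2010111I01Rik with 28 stood above Sfi1 with 27. In the conservative list 2 moved, Ncor2 to 5 and Ncam1 to 4.

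The strongest distal regions were short intergenic intervals. The highest mean enrichment was 52.5 ± 1.94 (SD, n = 2) on chromosome X from 143482936 to 143483180, 35.5 kb from Pak3. Next were 46.6 ± 1.21 on chromosome 2 from 69355470 to 69355735 near Abcb11, and 37.1 ± 3.56 on chromosome 10 from 96077549 to 96077951 near Gm5426 (SD, n = 2 each). Of the 10 strongest, 6 matched mitochondrial DNA around the summit, including those near Abcb11 and Gm5426, and are uncertain as nuclear accessible sites.

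Several transcription factor motifs were centred on distal summits. The CTCF motif, of the protein at loop anchors, occurred within 50 bp of 1.98% of distal summits in replicate 1 and 1.67% in replicate 2, 20.3-fold and 16-fold over flanks. The AP-2 motif, of a family required in the neural crest, occurred at 6.78% and 6.5% (3.29-fold and 2.89-fold), while a stricter AP-2 motif was not called (2.2-fold and 1.37-fold, adjusted p = 0.085 and 0.663 by permutation) except in the pseudoreplicated lists. The ETS motif occurred at 0.778% and 0.746% (3.43-fold and 5-fold). The CAGCTG E-box occurred at 14.3% and 15.2% (2.57-fold and 2.63-fold), the CCAAT box at 11.7% and 12.6% (2.66-fold and 2.61-fold), the AP-1 motif at 3.76% and 3.1% (2.42-fold and 2.04-fold) and the TEAD motif at 3.83% and 3.79% (2.11-fold and 2.1-fold). The CATCTG E-box was 1.15-fold and 1.29-fold over flanks. The GATA motif (0.206-fold and 0.361-fold) and the homeodomain motif (0.449-fold and 0.458-fold) were less frequent at summits than at flanks.

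In total 8 motifs were higher and 2 lower among 27, by the permutation test over chromosomes with adjusted p of at most 0.0404. Summit windows had a GC content of 59.3% and 59.0% against 48.5% and 48.4% in flanks. With the reversed motif in the same windows as background, which keeps the base composition though not the CpG content, neither lower call held, with the homeodomain motif turned to 3.43-fold and 1.8-fold and the GATA motif at 0.538-fold and 0.65-fold. The ETS motif stayed higher at 2.4-fold and 2.08-fold but passed in replicate 1 alone (adjusted p = 0.0423 and 0.108 by permutation). The other 7 higher calls remained, and RUNX and MEF2 motifs were called higher as well. The MEF2 motif stood at only 10 and 11 summits there, against 0 for its reversed form. Over flanks it lay at 1.33-fold and 2.2-fold without a call. The reversed CTCF motif also stood at 0, against 61 and 56 summits with the motif. A motif and its reversed form can also differ in frequency away from summits. In replicate 1 flanks held the CAGCTG E-box at 5.58%, against 0.259% of summits for its reversed form. For TEAD these shares were 1.82% and 0.422%. Of the higher calls that remained, only the CCAAT box went the other way in that replicate (4.4% and 4.87%). Results against the reversed motif therefore cannot settle whether GC content accounts for a call. The CTCF, AP-1, TEAD and CATCTG calls ended in the stronger 50% of regions, the ETS, TEAD and CATCTG calls with a 25 bp window, and the CATCTG call also without mitochondrial-like regions and with every summit. The stronger 50% held only 596 and 659 distal regions, against 3083 and 3353 in the main lists. Calls lost there thus do not show that a motif is absent from strong distal sites. The CATCTG call was close to the threshold in replicate 1 (adjusted p = 0.0404 by permutation). Only 12 distal regions of each replicate were mitochondrial-like.

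**Figure D3:**
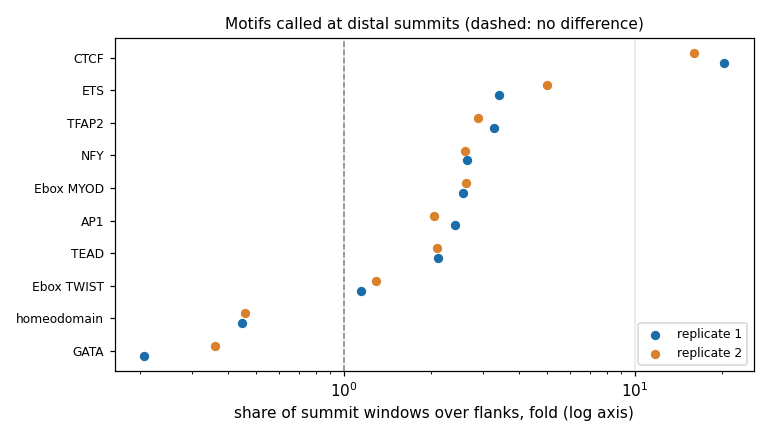
Share of distal summit windows with a motif over the share in flanks (horizontal axis, fold, log scale) in replicate 1 and replicate 2, for the motifs called in both. CTCF lies at 20.3-fold and 16-fold, and GATA and the homeodomain motif lie below the dashed line of no difference.

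The 2 pools were also set side by side, to ask whether the dissected cell types differed. With 1 library on each side there is no test, and the enrichment values were made separately for each list. Among 10745 shared regions the log2 ratio of replicate 1 to replicate 2 had an SD of 0.28 around its median of -0.16. For the 11 gene lists with at least 3 genes that had a shared distal region, the median ratio stayed within the central 95% of matched random sets. The FGF pathway lay at the 4.04 percentile (median log2 ratio -0.19 relative to that overall median) and the BMP and TGF-beta pathway at the 92.9 percentile (0.13 on the same scale). In the pseudoreplicated lists 3 of 26 gene lists fell outside that range, against 0 of 11 above: osteoblast and leukocyte genes towards replicate 2 and sensory neuron genes towards replicate 1. Some random sets also fall outside a central 95% range, so a few such lists do not by themselves show a difference between the pools. Nor can 1 library on each side show that the pools agree in cell types. Osteoblast genes lay at the 2.25 percentile and sensory neuron genes at the 97.9 percentile, near its edges. The leukocyte list rested on 6 regions at 5 genes. The single region most in favour of replicate 1 lay in an intron 19.5 kb from the nearest TSS, of Rab6b, with an enrichment of 7.05 against 4.12. The one most in favour of replicate 2 lay 77.0 kb from Tbl1x, with 12.9 against 2.89.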

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

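A signal stood in a part of the data that the comparisons do not use. The ranked list of the pooled reads, before thresholding, held 233 summits on sequences not placed on a chromosome, of 91083 summits in all, with a median enrichment of 2.61 against 3.14 for the whole list. The thresholded lists held none of them.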

How the results depend on the processing

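Leaving out mitochondrial-like regions and counting every summit were chosen after seeing the data. The depth of the libraries is unknown, and the length of the peak list was the choice that moved most results. The cause of each change below was not tested, except that longer lists hold weaker regions by construction. No call became a call in the other direction, but some values changed side without one. The homeodomain motif, below flanks, lay at 3.43-fold and 1.8-fold against the reversed motif. In the stronger 50% of regions the CATCTG E-box lay at 0.818-fold and 0.765-fold without a call. The BMP and TGF-beta list had 0 distal regions there in both replicates, with 1.22 and 1.36 expected and 0 inside the random range, so this shows no change of direction. The EBF motif, 0.696-fold and 0.48-fold and not called, was called higher in pseudoreplicated lists (1.64-fold and 2.03-fold).

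The 16646 series regions became 50165 in the replicated and 51725 in the pooled pseudoreplicated list. Overlap between replicates was 79.1% when at least 50% of both regions had to overlap, 63.3% in pseudoreplicated lists and 87.1% in the stronger 50% of regions. The promoter share was 37.1% in pseudoreplicated lists, 90.2% in the stronger 50%, 72.2% and 77.4% with windows of 500 and 2500 bp, 68.3% with the longest transcript only, 79.8% with every summit, and 74.3% to 75.6% with each replicate left out in turn.

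The count of lists with more distal regions was 0 in the stronger 50%, where lists held too few regions to weigh, 2 with every summit, 3 with the longest transcript only or a reach of 500 kb, and 6 in pseudoreplicated lists (3 kept, with jaw patterning, orofacial clefting and WNT added), against 4, and 4 to 5 with each replicate left out. With all genes within 50 kb, 1 list was lower (Hox groups 5 to 13), against 0. Lists with a higher promoter share numbered 4 in pseudoreplicated lists (facial mesenchyme, orofacial clefting, BMP and TGF-beta added) and 2 with a 2500 bp window, the longest transcript or every summit, against 1, and 1 to 2 with each replicate left out. Lists with a lower share numbered 7 in pseudoreplicated lists, 14 in the stronger 50% (jaw patterning, cartilage and forebrain added) and 13 with a 500 bp window (forebrain and heart added), against 11, and 11 to 12 with each replicate left out. Counts of distal regions at the 15 named genes moved by over 1.5 times for 2 genes in the conservative list, 9 at an IDR of 0.01, 14 in the replicated list and 14 in the pooled pseudoreplicated list. Higher motifs numbered 13 in pseudoreplicated lists, 4 in the stronger 50% and 5 with a 25 bp window, against 8, and 9 with each replicate left out. Lower motifs numbered 1 in the stronger 50%, 1 with a 25 bp window and 0 against the reversed motif, against 2. Lists outside the random range between the pools numbered 3 of 26 in pseudoreplicated lists, against 0 of 11. No paired analysis was possible because there was 1 group.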

Other observations

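The tests of mitochondrial matches, nuclear copies, CpG content, open promoters and the list without its top gene were fixed before their results were seen. The versions in which the random lists also lost their top gene or top 3 genes, and the comparison of motifs in shared and unshared regions, were chosen after results were seen. For the osteoblast list without its 3 top genes, the rule first written read the result as a fit with 3 genes carrying the list. A condition on the fold was added after that result was seen, and it changed the reading to undecided. The reading of the list without its top gene was also changed after results were seen, as described below.

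The RUNX motif, bound by the regulators of bone and cartilage differentiation, was unevenly spread between the pools. It was found at 73 distal summits of replicate 1 (2.37%) and 37 of replicate 2 (1.1%), and passed its permutation test against flanks in replicate 1 alone. Over flanks it lay at 2.21-fold in replicate 1 and 1-fold in replicate 2. Against the reversed motif it was higher in both replicates (6.08-fold and 3.36-fold, adjusted p = 6.7e-05 and 0.000733 by permutation). Flanks of replicate 2 held the motif as often as its summits, so that ratio shows no enrichment at replicate 2 summits. In the longer pseudoreplicated lists RUNX was higher over flanks in both replicates, so there the motif was not limited to replicate 1. In distal regions shared by both replicates the shares were 1.68% and 1.42%. In regions called in 1 replicate only they were 3.58% in replicate 1 (40 of 1117) and 0.649% in replicate 2 (9 of 1387). AP-1 motifs stood at 5.46% and 3.53% in such regions, and TEAD motifs at 4.12% and 4.33%. RUNX was picked from 27 motifs after its values were seen, regions are not replicates, and the difference between the pools was not tested. The osteoblast list carried 13 distal regions in each replicate.

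The strongest distal regions were weighed as a technical pattern. Of the 10 strongest, 6 matched the mitochondrial genome, with identities from 94.5% to 100%, which fits nuclear copies of mitochondrial DNA drawing reads from the abundant organelle. Over the whole lists only 12 distal regions of each replicate matched (0.389% and 0.358%). A second nuclear copy was found for 4 of the 10, all 4 of them mitochondrial matches, which leaves open whether nuclear duplication adds to the pattern. The other 4 strongest regions matched neither. No biological explanation was tested.

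The low promoter shares of tissue-specific lists could follow from their CpG-poor promoters, since CpG-rich promoters are often open in every tissue. With each list compared to genes of similar CpG content by a permutation test, 8 of the 11 lower lists were still lower in both replicates, which argues against CpG content as the whole cause. A further 4 lists, jaw patterning, sensory neuron, forebrain and WNT pathway genes, were not called in the main comparison and were called lower with this matching. For Hox groups 5 to 13 matched genes had a promoter region in 71.6% and 72.6% of cases, against 0 observed. The calls for skeletal muscle, liver and leukocyte genes ended, and leukocyte genes had a matched share of only 4.5% in replicate 1. Thinly represented cell types and limited depth stay open as untested explanations.

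The excess of distal regions at signalling and osteoblast genes was weighed against open promoters and against single genes. With matching on the presence of a promoter region as well, 3 of the 4 lists were still called, and the FGF list ended with 2.8-fold in replicate 1 (adjusted p = 0.0803 by permutation). Without the gene with most regions, 0 of the 4 lists were called, with folds between 2.82 and 4.24, against 3.24 to 4.7 with every gene. That test removes the top gene from the list and not from the random lists, so it leans towards ending calls. The rule fixed beforehand read this loss of calls as a fit with a few genes carrying a list. Because of the lean, the reading was changed to undecided after the trimmed random lists gave the opposite result. When each random list also lost its top gene, 4 of 4 were called, at 4.34-fold to 7.14-fold, and so was the WNT list. This version leans towards keeping calls. If 1 gene carried a list, the other genes would keep their own top gene while each random list lost its own. For osteoblast genes in replicate 1 the matched mean fell from 0.167 to 0.0855 regions per gene this way. Whether the top gene alone carries a call was therefore not settled, although the remaining genes lay 2.82-fold to 4.24-fold above whole random lists. Regions lay at 12 and 14 of the 33 BMP and TGF-beta genes, 10 and 12 of 25 FGF genes, 8 and 9 of 18 hedgehog genes, and 5 of 18 osteoblast genes in both replicates. When each list and each random list lost their 3 top genes, all 3 pathway lists were still called, at 6.4-fold to 18.1-fold. These folds are over trimmed random lists and cannot be set beside those with every gene. This version also leans towards keeping calls. The remaining genes had 0.467 and 0.5 regions per gene (BMP and TGF-beta), 0.409 and 0.455 (FGF) and 0.533 and 0.6 (hedgehog). Whole matched lists had 0.196 and 0.209, 0.184 and 0.198, and 0.188 and 0.201. The remaining genes thus stayed above whole matched lists, a difference that was not tested. Of the 13 osteoblast regions in each replicate, all but 2 and 3 lay at Col1a1, Col1a2 and Sp7. Without these genes the osteoblast list was past the threshold in 0 replicates (adjusted p = 0.448 and 0.255 by permutation). It lay at 6.75-fold and 8.36-fold over trimmed random lists, which kept only 0.0198 and 0.0239 regions per gene. The remaining 15 osteoblast genes had 0.133 and 0.2, against 0.166 and 0.177 in whole matched lists. No clear excess was thus seen outside the 3 genes. That goes with 3 genes carrying the osteoblast call, but 2 and 3 regions are too few to decide.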
